A study of Ulva lactuca with 4 samples.

How the data were processed

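RNA was sequenced from thalli of Ulva lactuca, a sheet-like green seaweed of the intertidal zone, under 4 conditions with 1 library each. Per the labels, the control thalli stayed under water, and the other libraries came from thalli held at 20% moisture, with a desiccation of 24 h for 1 library, 36 h for another and 72 h for the last. The labels do not say whether the control was sampled at a time matched to each duration. Its title begins with 24_6 and those of the other libraries with 24_0, 36_0 and 72_0, and the labels do not explain these numbers. RNA was extracted with a commercial plant RNA kit and made into libraries with a TruSeq-type kit, per the labels' protocols. The libraries had served in an earlier series and were set here against another de novo assembly, per the series' design text. The submitters' processing notes name cutadapt, Bowtie2 and DESeq. Their versions and settings, the assembler, the libraries that went into the assembly and the treatment of reads that fit several contigs are not given in the sources used here.

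The 5 tables used here each compare a pair of libraries over the same 105451 contigs. Each table holds read counts per contig and library, not normalized, as deposited by the authors. The scaled values beside them are a signal on the scale of counts, which the authors obtained by dividing each library by a size factor, per the file headers. The fold change between the libraries of a pair was computed by the authors and deposited as a linear ratio. Each contig also has a p-value and an adjusted p-value deposited by the authors, and a status of up, down or not significant. The table of 24 h against 36 h was not used here. That pair was compared through the counts, since the 6 repeated count columns of a library were identical between tables in 6 of 6 cases. All columns of per-sample values in the tables were used.

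The contigs carry identifiers of the assembly and no gene name or protein description in the tables used here. The 22 gene lists fixed before the data were examined could therefore not be applied, and no contig was given a function or an organism. Contigs with the same c and g number form 1 cluster of the assembly. There were 70737 clusters, of which 59872 held 1 contig and the largest held 33. A cluster can stand for 1 gene split over several contigs, so contigs of a cluster are not independent.

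Counts were scaled by median-of-ratios size factors over the 4 libraries, which were 0.885 for the control, 1.13 for 24 h, 1.15 for 36 h and 0.89 for 72 h. For the counts of differing contigs, the log2 of the ratio of (scaled count + 1) in the second library of a pair to that in the first was taken. The ratios printed for named contigs are those of the scaled counts with nothing added, which lie further from 1 where a library has few reads. A contig was counted as different when it was at least 4-fold apart and had at least 50 scaled counts in 1 of the 2 libraries. With 1 library per group there are no residual degrees of freedom, so no test across contigs was run and no p-value was computed. The differences have no replicate check, and they compare libraries, not conditions. Ratios of 2 counts have exact Clopper-Pearson 95% intervals, which cover counting error only and neither the spread between thalli nor duplicate PCR reads. For a count of 0, a limit was computed by putting 3 counts in its place. It takes the larger count as it stands, and the lower end of the 95% interval lies below it, for c22563_g1_i1 at 72 h over the control at 1497 against a limit of 1841.

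The rule for named contigs was set before the data were examined. Where tables carry no annotation it takes at most 2 contigs higher and 2 lower per comparison, ranked by the bound of the 95% interval of the ratio that lies nearest to 1. The counts of contigs shared between durations were set beside the overlap of independent lists and beside 100 simulated sets of unchanged libraries. In each set all libraries, the control included, were Poisson counts around the mean of the real libraries, and the durations shared 1 simulated control. The rule of size was tested on simulated data for each of the 6 pairs. It recovered 100 of 100 contigs simulated at 8-fold and 0 of 100 simulated at 2-fold in each pair, and 0 of the unchanged contigs passed it. The simulated counts carried counting error alone, so this tests the calculation and not the rule under a spread between thalli.

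Alternatives set before the data were examined were filters of 10 and 200 scaled counts or none, pseudocounts of 0.5 and 5, scaling by library totals, by the upper quartile or by TMM, thresholds of 2-fold and 8-fold, the authors' deposited fold change, and other thresholds on the authors' adjusted p-value. Alternatives chosen after seeing the data were the sum of contigs per cluster, the removal of contigs read in 1 library alone, a count minimum in any of the 3 libraries for shared contigs, and the authors' status column. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with TMM factors from edgeR 4.0.16 in R 4.3.3 and plots from matplotlib 3.10.9.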

Results

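The transcriptome of Ulva lactuca thalli was measured by RNA sequencing in 4 libraries, 1 from thalli kept under water (the control) and 3 from thalli held at 20% moisture, with desiccation lasting 24 h in 1 library, 36 h in another and 72 h in the last. The study asked which genes differ in expression during desiccation. When the control was sampled relative to each duration is not given in the sources used here, so a difference from it can hold the sampling time as well as the desiccation. The libraries held 52643595 reads counted on contigs for the control, 74243310 for 24 h, 71024673 for 36 h and 53279365 for 72 h. Reads fell on 81547 of the 105451 contigs in the control, on 87832 at 24 h, on 87806 at 36 h and on 98649 at 72 h. The 46571 contigs with at least 50 scaled counts in at least 1 library took 99.2% or more of the reads of each library. There were no replicates, so no difference below could be set against a spread between samples, and all intervals cover counting error only. Contigs are named by their assembly identifiers, because the tables used here do not pair them with genes.

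After 24 h of desiccation, 3591 contigs were at least 4-fold higher and 3277 at least 4-fold lower than in the control, of 41478 with enough counts. The contigs higher at 24 h took 21.0% of the reads of that library and 3.27% of those of the control. The contig c42739_g1_i1, 5.52-fold above the control and singled out after its values were seen, took 6.07% of the reads at 24 h. Without it the shares were 14.9% and 2.05%. The contigs lower at 24 h took 1.11% of its reads and 11.7% of those of the control. The contig c19303_g2_i1 had 1 read in the control and 9121 at 24 h, a ratio of 7167 (95% interval 1286 to 283126). The contig c13936_g1_i2 had 4 reads in the control and 16213 at 24 h, a ratio of 3185 (1244 to 11691). On the other side, c19261_g3_i1 was 7156-fold lower at 24 h (5013 to 10607), with 168708 reads in the control and 30 at 24 h. The contig c57626_g1_i1 was 4513-fold lower (3600 to 5738), with 265993 reads in the control and 75 at 24 h. Its adjusted p-value in the authors' deposited table, which came from DESeq per the submitters' processing notes, was 0.176. Of the contigs with enough counts, 60.9% lay within 2-fold of the control. The balance of directions depended on the scaling: with library totals, 3166 contigs were higher and 3723 lower.

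After 36 h, 3044 contigs were at least 4-fold higher and 2740 lower than in the control, of 41280. The contigs higher at 36 h took 8.63% of the reads of that library against 1.24% in the control, without c42739_g1_i1, which was 3.48-fold above the control at 36 h, and those lower took 0.765% against 7.08%. The contig c377_g1_i2 had 1 read in the control and 5579 at 36 h, a ratio of 4308 (773 to 170172). The contig c13936_g1_i2, named above for 24 h, had 9060 reads at 36 h, a ratio of 1749 (683 to 6420). The contig c19261_g3_i1 was 4966-fold lower than in the control (3699 to 6835), with 44 reads at 36 h. The contig c43182_g1_i1 was 4963-fold lower (2698 to 10350), with 38318 reads in the control and 10 at 36 h. Here too the balance of directions turned with the setting, to 2909 higher and 2955 lower with library totals, to 7927 and 8353 at a threshold of 2-fold, and to 1312 and 1424 when contigs were summed per cluster.

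After 72 h, 7245 contigs were at least 4-fold higher and 2645 lower than in the control, of 44612. Higher contigs made up 73.3% of the differing contigs, against 52.3% at 24 h and 52.6% at 36 h. Of the contigs higher at 72 h, 1925 had 0 reads in the control, against 392 of those higher at 24 h and 316 of those higher at 36 h. The contig c18556_g1_i1 had 5 reads in the control and 241745 at 72 h, a ratio of 48060 (20594 to 148017). It had 67 reads at 24 h and 55 at 36 h. The contig c22563_g1_i1 had 0 reads in the control and 5556 at 72 h, at least 1841-fold higher. The contigs c57626_g1_i1 and c19261_g3_i1 were 8632-fold (6081 to 12705) and 5475-fold (3857 to 8058) lower than in the control, each with 31 reads at 72 h. More contigs were higher than lower under each scaling tried, with 6397 higher and 3234 lower for the upper quartile. Without contigs read in 1 library alone, 5585 were higher and 2585 lower.

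**Figure D1:**
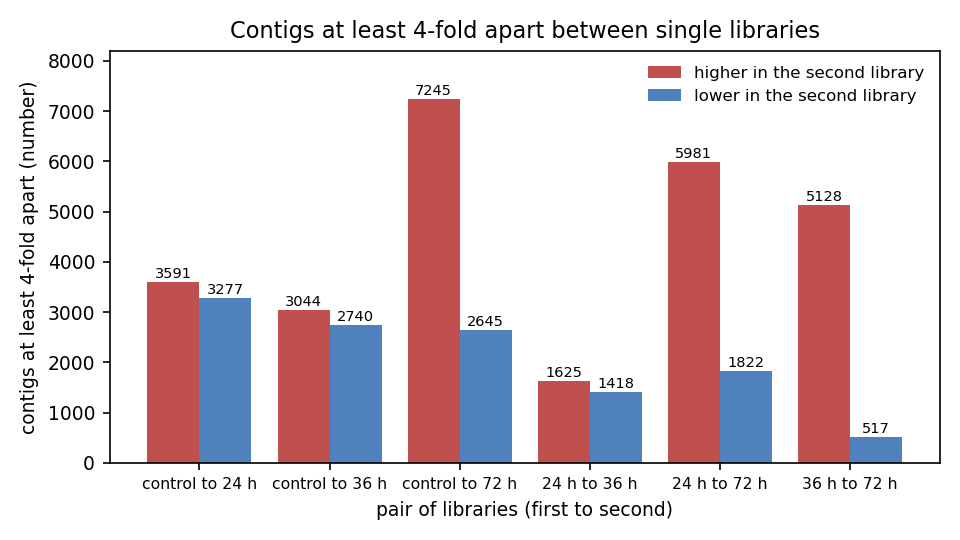
Number of contigs at least 4-fold higher (red) or lower (blue) in the second library of each of the 6 pairs, with at least 50 scaled counts in 1 of the 2 libraries and 1 library per condition. The bars for higher contigs in the 3 pairs that end at 72 h stand at 7245, 5981 and 5128, above those for lower contigs at 2645, 1822 and 517.

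The desiccated libraries were also compared with each other. Between 24 h and 36 h, 3043 of 40776 contigs were at least 4-fold apart, 1625 higher and 1418 lower at 36 h. Summed per cluster, 708 were higher and 869 lower, and at a threshold of 2-fold 5424 contigs were higher and 5660 lower. The contig c21730_g1_i4 had 0 reads at 24 h and 1674 at 36 h, at least 548-fold higher, and it had 3184 reads in the control. The contig c25906_g1_i7 had 25 reads at 24 h and 9855 at 36 h, a ratio of 387 (262 to 599), and 22749 reads in the control. The contigs c19661_g1_i1 and c19661_g1_i2, which belong to 1 cluster, had 4017 and 4001 reads at 24 h and 0 at 36 h, at least 1363-fold and 1357-fold lower. In the control each had 1 read.

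Between 24 h and 72 h, 5981 contigs were higher and 1822 lower at 72 h, of 44430. Between 36 h and 72 h, 5128 were higher and 517 lower, of 43703, so that 90.8% of the differing contigs were higher in the later library. With the upper quartile as scaling, the latter pair gave 4290 higher and 793 lower. The contig c18556_g1_i1 had the highest lower bound of the interval in both comparisons, with ratios of 4564 (3594 to 5890) over 24 h and 5659 (4347 to 7512) over 36 h. The contig c28174_g2_i5 had 0 reads at 24 h and 3015 at 72 h, at least 1271-fold higher. The contig c26140_g1_i2 had 2 reads at 36 h and 21576 at 72 h, a ratio of 13889 (3844 to 114690). That contig had 8358 reads in the control and 1243 at 24 h. The contig c19661_g1_i3 had 3808 reads at 24 h and 0 in the other 3 libraries, at least 1003-fold lower at 72 h. Its cluster partner c19661_g1_i1 had 1 read at 72 h, a ratio of 3176 (570 to 125459) in favour of 24 h. From 36 h to 72 h, c26840_g1_i1 was 335-fold lower (114 to 1628), with 1295 and 3 reads, and c27708_g1_i3 was 131-fold lower (96.5 to 183), with 6916 and 41 reads.

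Part of the contigs that differed from the control at 1 duration also differed at the others. Of the 3591 contigs higher at 24 h, 1915 (53.3%) were at least 4-fold above the control at 36 h and 2013 (56.1%) at 72 h. Of the 3277 lower at 24 h, 1516 (46.3%) were at least 4-fold below it at 36 h and 1360 (41.5%) at 72 h. The count minimum was not asked for at the second duration, so a few reads there could pass as higher where the control had 0. Lower contigs could not gain in this way, since their control count met the minimum. With the minimum met in both comparisons, 1624 of the 3591 were also higher at 36 h and 1761 at 72 h. The numbers of lower contigs did not change. Of the 7245 contigs higher at 72 h, 2107 (29.1%) were at least 4-fold above the control at 24 h and 2499 (34.5%) at 36 h. Their median log2 ratio to the control was 0.78 at 24 h, 1.15 at 36 h and 3.97 at 72 h. Of these contigs, 1660 had at most 3 reads in each other library, and their ratios at 24 h and 36 h rest on the pseudocount. Without contigs read in 1 library alone, the medians were 1.31, 1.80 and 3.29. Each group was selected on its ratio to the control in 1 library, which moves its median away from 0 there. All 3 ratios share the control library, so an error in a control count moves them the same way. The medians and the shares past 4-fold at the other durations can therefore be raised by the selection as well. Of the 46571 contigs with enough counts in any library, 1915 were at least 4-fold higher in all 3 desiccated libraries and 923 lower in all 3, and 16172 (34.7%) lay within 2-fold of the control in all 3. The number higher in all 3 has the same one-sided gain from contigs with few reads. The 1915 higher in all 3 are another set than the 1915 contigs higher at 24 h and 36 h above, with 1619 in common. Among the same 46571, contigs that were higher at 1 duration and within 2-fold of the control at the other two numbered 299 for 24 h, 70 for 36 h and 2372 for 72 h. Of the 2372, 1411 had at most 3 reads in each other library, too few to show a steady level there. Without contigs read in 1 library alone, the numbers were 290, 66 and 961. The corresponding numbers of lower contigs were 353, 122 and 159.

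**Figure D2:**
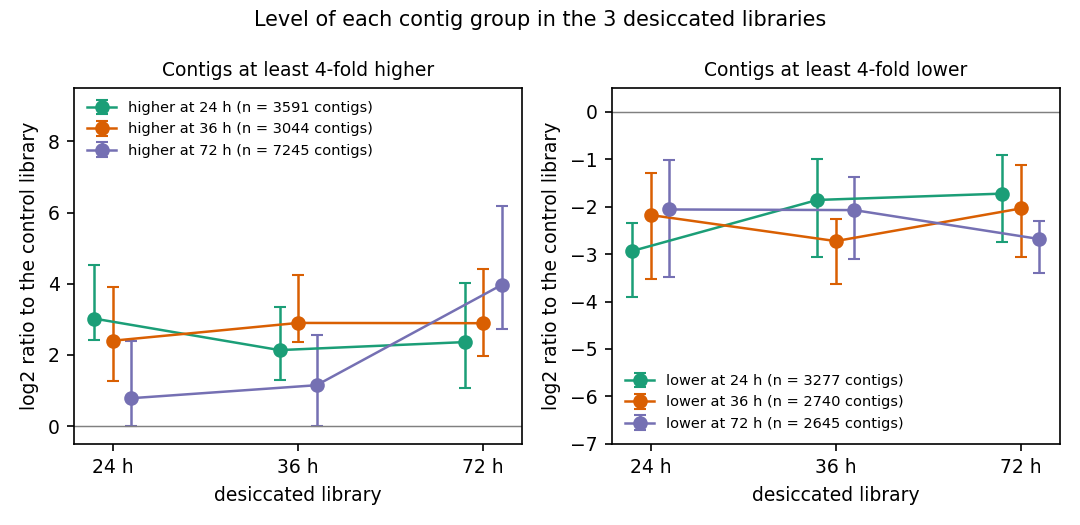
Median log2 ratio to the control (points; bars span the quartiles over contigs, not replicates) in the 3 desiccated libraries, for contigs at least 4-fold higher (left) or lower (right) at 24 h, 36 h or 72 h. The 7245 contigs higher at 72 h had medians of 0.78 at 24 h and 1.15 at 36 h, drawn towards 0 by the pseudocount for 1660 contigs with at most 3 reads in each other library. Each group was selected on 1 of its points, and all points share the control library, which entered the selection too.

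Among contigs with enough counts in both comparisons with the control, 1624 were higher and 1516 lower at both 24 h and 36 h. Independent lists of the same lengths would share 163 and 225. At both 24 h and 72 h, 1761 were higher and 1360 lower, against 250 and 216 for independent lists. At both 36 h and 72 h, 2084 were higher and 1398 lower, against 238 and 180. This count minimum leaves out contigs with few reads in the control that pass it at 1 duration alone. In the first pair it keeps 2714 of the 3591 contigs higher at 24 h and each of the 3277 lower ones. With 50 scaled counts in any of the 3 libraries in its place, 2079, 2359 and 2664 higher contigs were shared, against 293, 642 and 562 for independent lists. The ratio of shared higher contigs to independent lists was then lower in each pair, and their excess in number of contigs was larger. Part of that ratio under the first minimum therefore comes from the minimum. More contigs were shared lower than higher at 24 h and 36 h with library totals (1478 higher, 1736 lower), a filter of 10 (2644 and 2721) or cluster sums (663 and 869), and for each of the 3 pairs of durations at a threshold of 2-fold. Unchanged libraries, with the control simulated as well, shared 0 contigs in each of 100 draws. They carry counting error alone, which hardly ever gives a 4-fold gap at 50 scaled counts or more. This 0 was therefore close to fixed in advance and gives no baseline for the overlap. Part of the excess of shared contigs over independent lists may come from the shared control, which is 1 library and cannot be split.

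Some contigs were read in 1 library alone, with at least 10 reads there and at most 3 in each other library. They numbered 638 for the control, 718 for 24 h, 556 for 36 h and 7654 for 72 h. The 7654 contigs took 0.766% of the reads at 72 h. With each library thinned to the smallest total, the numbers were 816, 418, 322 and 7857. With at least 50 scaled counts the numbers were 60, 19, 15 and 1660, and the 1660 contigs at 72 h lay in 1163 clusters and had a median of 91.5 reads. In the other direction, 600 contigs had at most 3 reads in the control and at least 20 in each desiccated library. Missing in the same way from 1 desiccated library alone were 64 contigs for 24 h, 31 for 36 h and 36 for 72 h.

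**Figure D3:**
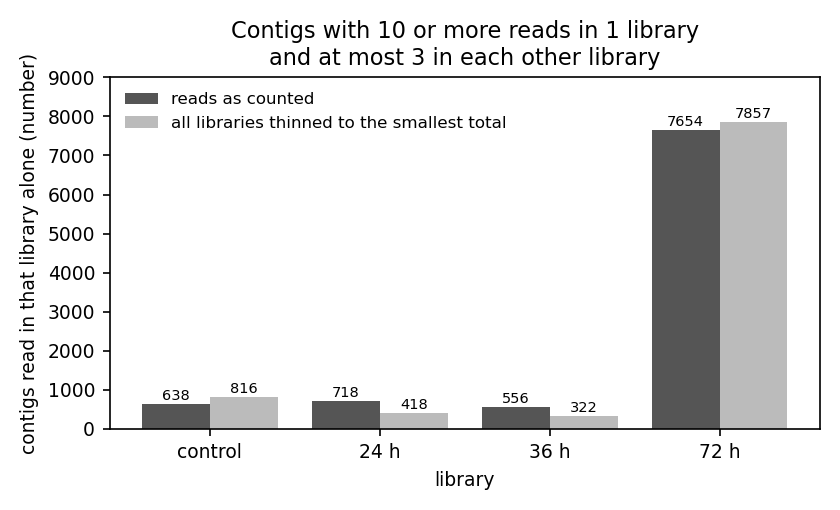
Number of contigs with at least 10 reads in 1 library and at most 3 in each other library, with the reads as counted (dark) and with all libraries thinned to the smallest total (light). The 72 h library holds 7654 and 7857 such contigs, and the highest count among the other libraries is 718 as counted and 816 after thinning.

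In each of the 5 of the authors' deposited tables used here, the contigs with an adjusted p-value under 0.05 were fewer than those past the 4-fold rule. There were 525 for the control against 24 h (304 higher, 221 lower), 413 against 36 h (308 higher, 105 lower) and 552 against 72 h (492 higher, 60 lower). In the authors' deposited tables of the desiccated libraries there were 634 for 24 h against 72 h (615 higher, 19 lower) and 1043 for 36 h against 72 h (1008 higher, 35 lower). Of the contigs so called, 100% were also at least 4-fold apart by the rule used here. In the authors' deposited tables, the status column called more contigs, between 2530 and 3392 per table. Its calls matched an unadjusted p-value of at most 0.05 with at least 100 reads in 1 of the 2 libraries for each contig of the 5 tables, a rule read from the values and not stated in the sources used here. With 1 library per condition, these p-values rest on a spread that no replicates measured.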

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

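The tests in this part were chosen after the results were seen, except that of RNA from 1 other organism in a fixed makeup, whose bound was set before its value was known. Contigs whose difference from the control changed direction between durations were counted, among contigs with 50 scaled counts in any library. At least 4-fold higher at 24 h and at least 4-fold lower at 72 h were 26, and 170 were lower at 24 h and higher at 72 h. With the count minimum met in both comparisons with the control, the numbers were 6 and 54. By that minimum, 1761 contigs were higher and 1360 lower at both 24 h and 72 h. Both ratios share 1 control library, whose errors move them the same way. Opposite calls also need a wide gap between 24 h and 72 h, and shared calls need none. The larger number with a shared direction is therefore in part built into the comparison. The change of direction was not tested, since each condition has 1 library.

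The first pattern weighed is the set of contigs read in the 72 h library alone. Deeper sequencing of that library is argued against, since it held 53279365 reads, 71.8% of the 74243310 of the deepest library. Other contigs of clusters that the remaining libraries also read account for few of the 2031 that share a cluster with another contig, since 3.74% of them (76) lay in clusters with over 10 reads in another library. The other 5623 of the 7654 were alone in their clusters, so this test does not bear on them. RNA of 1 other organism in a fixed makeup stays open: the counts at 36 h of 244 contigs strongly enriched at 72 h scattered around 1 ratio with a chi-square per degree of freedom of 118, above the bound of 2 set before, but 45 of those 244 contigs belong to the set, so that bound was set on the wrong contigs. That judgement was made after the value was seen. By the bound alone, the value would have argued against this explanation. RNA of several organisms, the choice of libraries for the assembly and transcription in the alga after 72 h of desiccation are candidate explanations that were not tested, and no gene names were at hand to part them.

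The second pattern is the set of 600 contigs missing from the control alone. Lower depth of the control is argued against, since with the read totals thinned to the smallest, the one property matched, 508 contigs were missing from it, 5.71 times the highest number of another library (89). Reads moved to other contigs of the same cluster are argued against as well: of 392 such contigs in clusters of several contigs, 1.79% (7) had a cluster sum within 2-fold. Expression in response to desiccation and a difference between the thalli sampled were not tested and may each contribute.

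The third pattern is in the authors' deposited tables, where 36 h against 72 h had more adjusted calls than the control against 72 h. More large differences with many counts between 36 h and 72 h are argued against, since 336 contigs were at least 16-fold apart with 1000 or more scaled counts there and 581 in the control against 72 h. At 16- to 32-fold and 1000 to 10000 scaled counts, 107 of 107 contigs were called for 36 h against 72 h and 0 of 163 for the control against 72 h, a gap of 100 percentage points. This is what a spread taken from the 2 libraries compared would give, and it suggests that the numbers of calls in these tables do not rank the sizes of the responses. No biological explanation was tested for this pattern.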

How the results depend on the processing

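The alternatives of summing contigs per cluster, leaving out contigs read in 1 library alone, taking the count minimum in any of the 3 libraries for shared contigs and using the status column were chosen after seeing the data. Of 133 recomputed counts of contigs, 70 stayed within 1.5 times the count reported in total and in each direction, and 63 did not. In what follows, pairs stand in the order control to 24 h, to 36 h and to 72 h, then 24 h to 36 h, 24 h to 72 h and 36 h to 72 h, and shared contigs in the order 24 h with 36 h, 24 h with 72 h and 36 h with 72 h. Filters and fold thresholds move the counts by construction, since they change which contigs can pass. A filter of 10 gave 11574, 11026, 22520, 6870, 18617 and 15547 contigs, and shared counts of 5365, 5485 and 6320. A filter of 200 gave 4692, 3562, 5691, 1741, 4195 and 2621, and shared counts of 2020, 2012 and 2211. No filter gave 17318, 17574, 34745, 11712, 28428 and 24703, and shared counts of 7775, 8527 and 10008, where low counts limit each ratio most. A threshold of 2-fold gave 16227, 16280, 20971, 11084, 17325 and 11931, and shared counts of 9468, 9147 and 10876. A threshold of 8-fold gave 3377, 2512, 5891, 1231, 4574 and 3816. Contigs summed per cluster gave 3178, 2736, 5075, 1577, 4198 and 3286, and shared counts of 1532, 1516 and 1656, out of fewer features. Upper quartile scaling gave 5083 for 36 h to 72 h, within 1.5 times the 5645 reported, with 793 lower in place of 517 and 4290 higher in place of 5128. It moved the median log2 ratio of that pair by -0.28, which takes contigs from the higher side and adds to the lower side.

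Some alternatives turned the balance of directions. Library totals did so for the control against 24 h (3166 higher, 3723 lower) and 36 h (2909 and 2955), and for the contigs shared by 24 h and 36 h (1478 and 1736). Cluster sums turned it for the control against 36 h (1312 and 1424), for 24 h against 36 h (708 and 869) and for the contigs shared by 24 h and 36 h (663 and 869). The 2-fold threshold turned it for the control against 36 h (7927 and 8353), for 24 h against 36 h (5424 and 5660) and for the 3 shared counts (4475 and 4993, 4491 and 4656, 5430 and 5446). In the 3 comparisons that end at 72 h, more contigs were higher than lower in each alternative run. A filter of 10 turned it for the contigs shared by 24 h and 36 h (2644 and 2721). The causes were not tested. Scaling moved the median log2 ratio of the contigs with enough counts in a pair by more than 0.1 in some cases. Library totals moved it by -0.15 for the control to 24 h and 0.14 for 24 h to 72 h. The upper quartile moved it by 0.10, -0.18, -0.24 and -0.28 for the control to 36 h, control to 72 h, 24 h to 72 h and 36 h to 72 h. Without contigs read in 1 library alone, 36 h to 72 h gave 3970 contigs in place of 5645. In the same setting 961 contigs in place of 2372 were higher at 72 h alone, and the medians of the contigs higher at 72 h were 1.31 in place of 0.78 at 24 h and 1.80 in place of 1.15 at 36 h, since contigs with few reads elsewhere drop out.

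In the authors' deposited tables, taken as control to 24 h, to 36 h and to 72 h, 24 h to 72 h and 36 h to 72 h, an adjusted p under 0.01 left 349, 279, 295, 405 and 696 calls. An adjusted p under 0.1 gave 814 for 24 h to 72 h. The status column gave 3127, 2530, 3392, 3212 and 3127. These follow from the thresholds. For the named contigs, 113 of 120 recomputed ratios stayed within their counting interval. The other 7 were under a pseudocount of 5, for contigs with few or no reads in 1 library, and 0 of the 120 changed direction. These contigs were picked for extreme ratios, which the alternatives tried could not turn, so this says nothing about other contigs. The median values of the gene lists, the removal of contigs by taxon and the sum of contigs by protein description were not run, because the tables used here name no proteins. No paired analysis was possible because each condition has 1 library.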

Other observations

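The contig c42739_g1_i1, singled out after its values were seen, had the most reads over the 4 libraries. It took 1.22% of the reads in the control, 6.07% at 24 h, 4.07% at 36 h and 1.38% at 72 h. Its scaled count was 5.52 times that of the control at 24 h, 3.48 times at 36 h and 1.14 times at 72 h. The contigs c50143_g1_i1 and c50143_g3_i1, next in abundance, took 4.0% of the reads each in the control, 2.68% at 24 h, 2.69% at 36 h and 3.54% at 72 h, and their counts differed by at most 40 reads in each library. How the authors' counting treated reads that fit both is not given in the sources used here.

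A set of contigs was abundant in 1 library, with at least 10000 reads there and at most 1% of that scaled level in each other library, a rule set after the values were seen. There were 6 for the control, which took 1.03% of its reads, 8 for 72 h, which took 0.684% of its reads, and 0 for 24 h and 36 h. The contig c57626_g1_i1 alone took 0.505% of the reads of the control, and c18556_g1_i1 took 0.454% of those at 72 h. For each 10000 reads of c19261_g3_i1 in the control there were 1.78 at 24 h, 2.61 at 36 h and 1.84 at 72 h. Over the 6 contigs of the control, these values lay between 1.17 (c57626_g1_i1 at 72 h) and 9.67 (c24708_g1_i1 at 36 h). Whether reads this few reflect expression in the desiccated thalli was not tested.

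Contigs that were the only one of their cluster differed more often than contigs of larger clusters. With 1000 or more scaled counts, 33.4% of 770 single contigs and 14.2% of 14603 contigs of larger clusters were at least 4-fold apart between the control and 24 h. Between 36 h and 72 h the shares were 12.9% of 658 and 4.94% of 13765. Among contigs past the 4-fold rule in clusters of 2 or more, the cluster sum lay within 2-fold for between 2.52% and 6.09%, depending on the pair.

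The ratio of the size factors in the authors' deposited tables was 1.25 for both 24 h and 36 h over the control and 1 for 72 h, equal to the median ratio of reads over contigs read in both libraries. These read ratios were held by 400, 383 and 3567 contigs. For 24 h to 72 h and 36 h to 72 h the ratios of the authors' size factors were 0.831 and 0.772, also equal to the median ratio of reads, which 0 and 1 contigs held. The factors computed here gave 1.27, 1.30, 1.01, 0.791 and 0.777.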
